A study of Anopheles darlingi with 9 samples.

How the data were processed

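The series holds 9 RNA-seq libraries from midguts of adult female Anopheles darlingi, a malaria mosquito of Central and South America, with 3 libraries in each of 3 feeding groups. Each library was made from total RNA of a pool of 30 midguts, taken from females 3 to 5 days old and dissected 18 to 24 hours after the meal, per the labels. The series description states that the 3 replicates of each group were independent biological replicates. Groups were taken from the treatment given in each sample's labels, and replicate numbers from the sample titles.

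The deposited values are raw fragment counts per gene in 1 table of 10976 gene models, with the position, strand, exons and length of each. Per the submitters' processing notes, the reads were handled with FastQC 0.11.5, Trimmomatic 0.36, HISAT2 2.1.0 and featureCounts 1.5.3. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so positions are printed as the deposited table gives them. Gene lengths, given as summed exon lengths, were multiples of 3 in 95.8% of models, so most models appear to hold only coding sequence. In 815 models no library had a count. The table pairs its identifiers with no gene names, and 0 of the 10976 identifiers matched the reference gene table used here, which describes the assembly idAnoDarlMG_H_01. Gene names and functions are therefore not given, and the 40 gene lists fixed in advance, with the markers of other tissues among them, were not tested, neither by camera with a preset or estimated inter-gene correlation or a replicate block, nor by fry.

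Total counts per library ran from 8072117 to 23410800. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom between replicates was 53.2, so each library was counted as 1 replicate. Count-ratio intervals and detection floors were taken on counts pooled over the libraries of a group. They cover counting error only and leave out the spread between libraries. Amplified copies could not be told apart either, because the fragments carry no molecular identifiers.

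Differences were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersion, TMM scaling and the filterByExpr filter at a minimum count of 10. The 9 libraries entered 1 fit with the 3 groups, without covariates, so that the groups shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and genes with an adjusted p under 0.05 are described as higher or lower. Normalised expression is given in edgeR's CPM unit on TMM-scaled totals, as mean ± SD with n = 3. Standard errors of log2 fold changes were derived from the F statistic. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the whole group. Where it had very few, the ratio of pooled counts is given with its exact binomial 95% interval.

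Genes were named by a rule set before the data were examined. In each comparison, the 2 genes with the largest rise and the 2 with the largest fall are named. They had to pass the threshold, to have a mean of at least 8 CPM over the 6 libraries compared, and to show no overlap between the groups. Where none passed, the 2 with the smallest p in each direction are given as values. Chance alone leaves 3 libraries without overlap against 3 in 10% of genes.

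The alternatives chosen in advance were DESeq2 size factors, upper-quartile factors, TMM without the 20 most abundant genes, no filter, and a filter of 1 CPM in 3 libraries. DESeq2 1.42.0, limma-voom from limma 3.58.1, a replicate block, fits of only the 6 libraries compared, edgeR's glmTreat against a fold of 1.5, an adjusted p of 0.01, and leaving out each library were also among them. Overlap between the comparisons against sugar-fed midguts was set beside 20 simulations of unchanged groups against the same libraries. Whether neighbouring genes changed together was tested with 10000 permutations of the calls over the tested genes.

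Replicate numbers were checked for pairing by correlating, across genes, the deviations of same-numbered libraries from their group means. Each of the 3 correlations had to exceed 0.1. This rule was applied after an exploratory run had shown the numbers of calls with and without a replicate block. Between the control blood-fed and the P. vivax-fed groups they were 0.609, 0.342 and 0.546, and in these deviations each of the 6 libraries was closest, among those of the other group, to the one with its own number, so those libraries were treated as paired by number in an alternative fit. The pairing rests on the titles' numbers and these correlations, since no label states a shared day, blood donor or mosquito batch. With only 3 libraries in each group few matchings are possible, so a same-number match can arise by chance and is weak support.

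The edgeR step was tested on simulated counts with 200 changed genes. These were drawn only from genes above a floor on expected counts, so the shares recovered do not cover genes with few counts. All libraries of a gene were simulated with the same spread, although sugar-fed library 1 lay apart in the data. With all 9 libraries, 2-fold, 4-fold and 16-fold changes were recovered in 0%, 2.99% and 90.9% of cases for control blood against sugar, over 7721 genes. For P. vivax blood against sugar the shares were 0%, 11.9% and 93.9% over 7781 genes, and for P. vivax blood against control blood 0%, 10.4% and 89.4% over 7750 genes. Without sugar-fed library 1, the shares were 4.48%, 53.7% and 87.9% for control blood against sugar over 7977 genes, and 8.96%, 65.7% and 90.9% for P. vivax blood against sugar over 7976 genes. For P. vivax blood against control blood in that setting they were 11.9%, 70.1% and 97.0% over 7970 genes. With only the 6 blood-fed libraries, that last comparison recovered 8.96%, 83.6% and 97.0% over 7477 genes. The 16-fold size and the settings with 8 and 6 libraries were added after a simulation with all 9 libraries had recovered few of the smaller changes.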

Results

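Midgut RNA was sequenced from Anopheles darlingi females given 1 of 3 meals. One group drank a 10% sugar solution, and a control group was fed through a membrane on blood in which the gametocytes, the parasite's sexual stages, had been inactivated. The other group was fed in the same way on blood infected with Plasmodium vivax, a human malaria parasite. Each group had 3 libraries. Total counts were 14049392, 10014350 and 11716229 in sugar-fed libraries 1 to 3, 14040360, 11766314 and 8072117 in the control blood-fed libraries, and 23410800, 12688551 and 11934190 in the P. vivax-fed libraries.

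The 6 blood-fed libraries resembled each other, and sugar-fed library 1 lay apart from the other 8. Correlations of log2 CPM across genes were 0.918 to 0.974 within a blood-fed group and 0.931 to 0.982 between the blood-fed groups. They were 0.902 between sugar-fed libraries 2 and 3, 0.824 to 0.921 between either of these and the blood-fed libraries, and 0.658 to 0.783 between sugar-fed library 1 and each other library. Sugar-fed library 3 was closest to P. vivax-fed library 1, at 0.921, and not to a library of its own group. Sugar-fed library 1 had a median of 11 counts per gene, against 34 to 147.5 in the others, and a TMM factor of 0.320 against 0.874 to 1.64. The mitochondrial scaffold, with 13 gene models, took 1.72% ± 0.623 of counts in sugar-fed, 2.03% ± 0.136 in control blood-fed and 1.97% ± 0.675 in P. vivax-fed libraries (SD, n = 3). The share was 0.999% in sugar-fed library 1 and 2.08% and 2.07% in libraries 2 and 3. With 3 libraries a group the exact permutation test used here cannot give a p under 0.1, so it decides nothing. In sugar-fed library 1 the mitochondrial gene at positions 1422 to 2963 had 712 CPM of the unscaled total, against 4436 to 8509 in the other 8 libraries. The gene at 203 to 1228 went the other way, with 709 against 133 to 379 CPM. These 2 genes were picked after the values were seen.

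**Figure D1:**
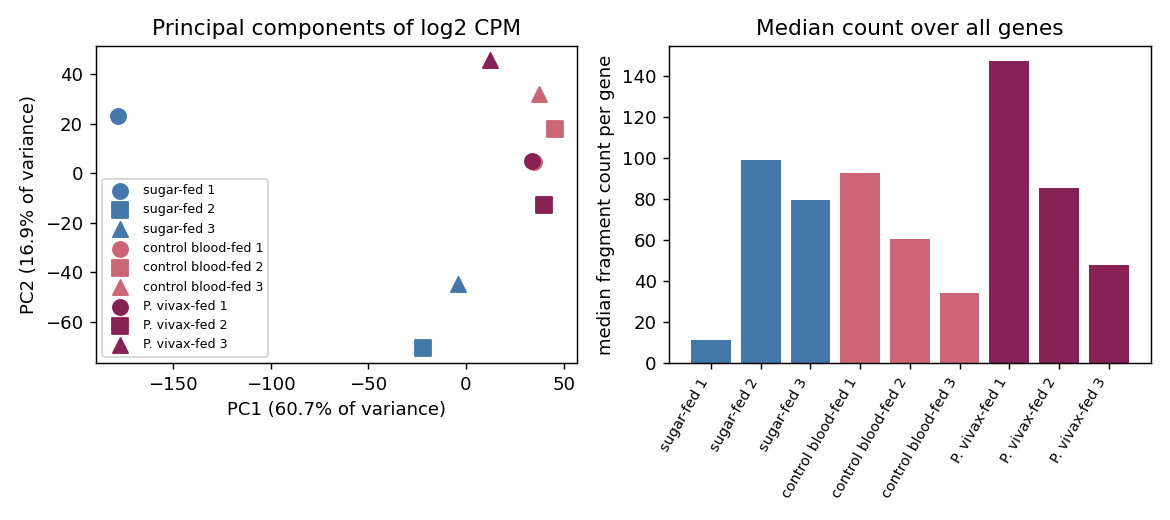
Left, the 9 libraries on the first 2 principal components of log2 CPM, coloured by meal and shaped by replicate number. Right, bars give the median fragment count over the 10976 genes in each library. The first component held 60.7% of the variance and set sugar-fed library 1, with a median of 11 counts, apart from the other 8.

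The comparison of control blood-fed with sugar-fed midguts asks what a blood meal changed in the absence of live parasites. Blood-fed midguts had 199 genes at higher and 243 at lower levels, out of 7831 tested by edgeR. Median log2 fold changes were 3.12 over the 199 higher and -2.79 over the 243 lower genes. Of these, 185 of the higher and 211 of the lower genes had a fitted change over 4-fold. Smaller changes may have been missed, since the test recovered 2.99% of simulated 4-fold and 90.9% of 16-fold changes. The simulations held fewer changed genes than were called here, which makes the adjusted p stricter. The share of real 4-fold changes that was missed therefore cannot be read from them. The 199 higher genes took 1.13% ± 0.643 of counts in sugar-fed and 10.4% ± 1.70 in control blood-fed libraries. The 243 lower genes took 2.05% ± 0.414 and 0.406% ± 0.108 (SD, n = 3).

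ADAC007363, a gene of 3 exons on scaffold 1564 (1785 to 2612, plus strand), had 0 counts in all 3 sugar-fed libraries and 38, 677 and 308 in the control blood-fed ones. Its rise after blood in pooled counts was 343-fold against a floor of 3 counts over the sugar-fed group. The exact 95% lower limit for counting error was 279-fold (edgeR adjusted p = 0.0333). ADAC001061 on scaffold 732 (47573 to 52665, plus strand) had 1, 1 and 0 counts in sugar-fed and 6, 986 and 339 in control blood-fed libraries. Its pooled ratio was 670, with a 95% counting interval of 185 to 5537 (edgeR adjusted p = 0.0423). Control blood-fed library 1 held far less of both genes than libraries 2 and 3. It had 2.17 CPM of ADAC007363, against 55.7 and 43.7, and 0.343 CPM of ADAC001061, against 81.1 and 48.1. Sugar-fed library 1 had 0.222 CPM of ADAC001061, so the pooled folds and limits do not hold in each library. The call of ADAC007363 was lost in 9 of 21 alternatives, with limma-voom (adjusted p = 0.0623) among them. That of ADAC001061 was lost in 10 of the 20 that tested it. Among them were limma-voom (adjusted p = 0.216), glmTreat (adjusted p = 0.0560) and edgeR without control blood-fed library 2 (adjusted p = 0.158). The fit of only the 6 libraries compared did not test this gene, so it was not called there either. ADAC000651 on scaffold 312 (62090 to 62991, minus strand) fell from 197 ± 236 to 6.30 ± 1.79 CPM, a log2 fold change of -4.95 (SE 0.91, edgeR adjusted p = 0.0202). ADAC008119 on scaffold 86 (36067 to 38573, minus strand) fell from 160 ± 166 to 5.17 ± 0.136 CPM, a log2 fold change of -4.95 (SE 0.75, edgeR adjusted p = 0.0149). On the TMM scale, the level of both falling genes was highest in sugar-fed library 1, at 469 CPM for ADAC000651 and 351 CPM for ADAC008119. Libraries 2 and 3 had 66.3 and 55.0 CPM of ADAC000651 and 79.4 and 50.1 CPM of ADAC008119. Raw counts in sugar-fed libraries 1 to 3 differed less, at 2111, 1088 and 883 of ADAC000651 and 1578, 1303 and 804 of ADAC008119. Much of the contrast in CPM therefore comes from the TMM factors of 0.320, 1.64 and 1.37. Each of these falls was lost in 5 of 21 alternatives. Without sugar-fed library 1 both still passed, with log2 fold changes of -3.25 and -3.64. None of the 4 genes overlapped another gene model. Of the 13 mitochondrial genes, 0 passed the threshold in edgeR, DESeq2 or limma-voom, and 1 had an unadjusted edgeR p under 0.05.

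Log2 fold changes over all tested genes trended with gene length (Spearman rho 0.215) and exon number (rho 0.266), and the median length was 1395 bases in the higher, 1365 in the lower and 1368 in all tested genes. Deviations from the group mean trended with length at -0.238 in sugar-fed library 1, and at 0.159 and 0.245 in libraries 2 and 3. The trend ran from -0.275 to 0.187 in control blood-fed and from -0.467 to 0.430 in P. vivax-fed libraries, so sugar-fed library 1 was not extreme in this. Deviations within a group offset each other, so their signs are not independent.

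The number of calls depended on single libraries. It was 921 without sugar-fed library 1 and 1603 without sugar-fed library 3, and it was 36, 16 and 12 without control blood-fed libraries 1, 2 and 3 and 178, 164 and 191 without P. vivax-fed libraries 1, 2 and 3, which share the estimate of the spread. DESeq2 called 1475 genes, a fit of only the 6 libraries compared called 20, glmTreat 237 and an adjusted p of 0.01 left 10. The balance of directions was not stable either: 528 higher and 947 lower with DESeq2, 173 and 127 with limma-voom, 120 and 383 without sugar-fed library 2, 429 and 1174 without sugar-fed library 3, and 20 and 0 with the 6 libraries.

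**Figure D2:**
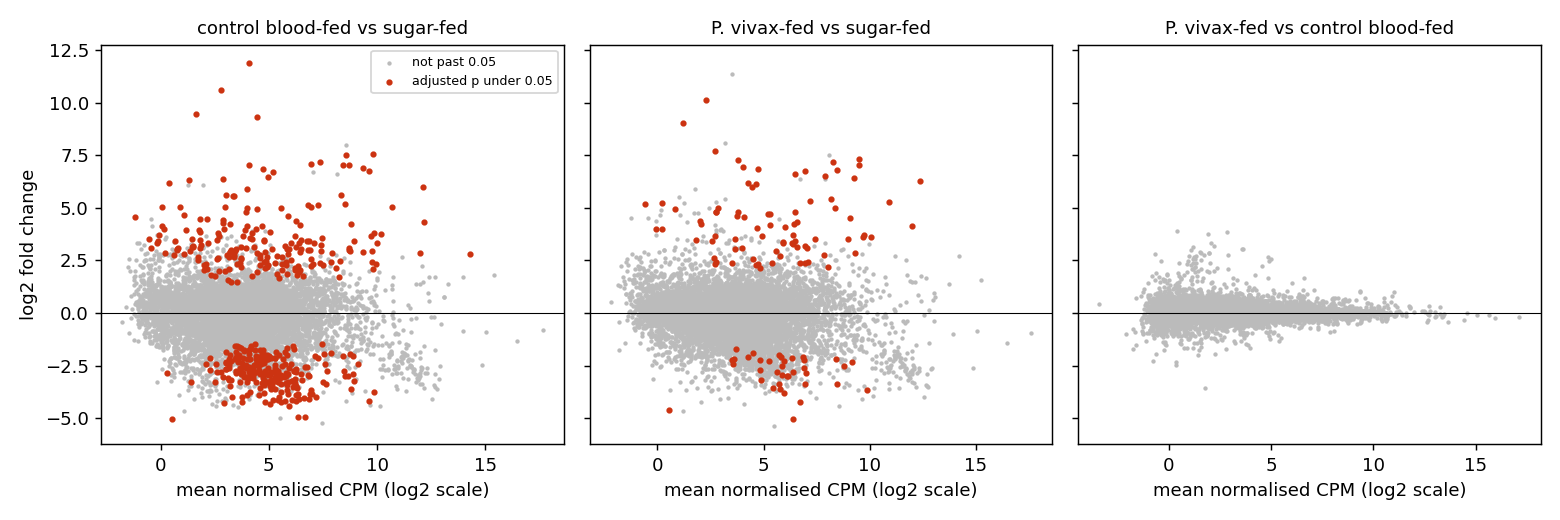
Each point is a gene, with the log2 fold change on the vertical axis and the mean normalised CPM of the groups compared on a log2 horizontal axis. Red points had an edgeR adjusted p under 0.05: 442 for control blood against sugar, 120 for P. vivax blood against sugar and 0 for P. vivax blood against control blood.

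Several of the genes that rose or fell after control blood lay side by side. Consecutive gene models on a scaffold that were called in the same direction formed 27 runs, 17 of them higher and 10 lower. Randomly placed calls also form some: rising pairs of tested neighbours numbered 20 against 3.46 permuted, and falling pairs 11 against 5.22. Falling pairs at least 1000 bases apart numbered 2 against 2.77 permuted. No rising pair was left without control blood-fed library 1, 2 or 3. The longest held 4 genes on scaffold 439 (40942 to 51204), with log2 fold changes of 2.27 to 4.02 and edgeR adjusted p-values of at most 0.0298. Mean levels in this run were 22.5 CPM in sugar-fed, 133 CPM in control blood-fed and 138 CPM in P. vivax-fed libraries. Gene by gene, they were 27.0, 61.6, 0.570 and 0.812 CPM in sugar-fed and 214, 297, 4.99 and 14.6 CPM in control blood-fed libraries. The run thus holds 2 genes near the floor in sugar-fed libraries. On scaffold 1 (430732 to 440177), 3 genes on the plus strand rose with log2 fold changes of up to 3.46 and edgeR adjusted p-values of at most 0.0426, and the most abundant of them went from 153 ± 63.9 to 1150 ± 401 CPM (SD, n = 3). On scaffold 1259 (4874 to 11699), 3 genes fell with log2 fold changes of -3.99 to -1.73. In sugar-fed libraries the first had 881 ± 989 and the second 269 ± 368 CPM, a spread above the mean, and the third 26.7 ± 4.36 CPM (SD, n = 3). After P. vivax blood, 2 of 4 genes were called on scaffold 439, 2 of 3 on scaffold 1 and 0 of 3 on scaffold 1259, where the log2 fold changes were -2.70, -3.76 and -1.48 (edgeR adjusted p = 0.0957, 0.0717 and 0.0755). These 3 regions were picked as the longest runs after the calls were seen.

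**Figure D3:**
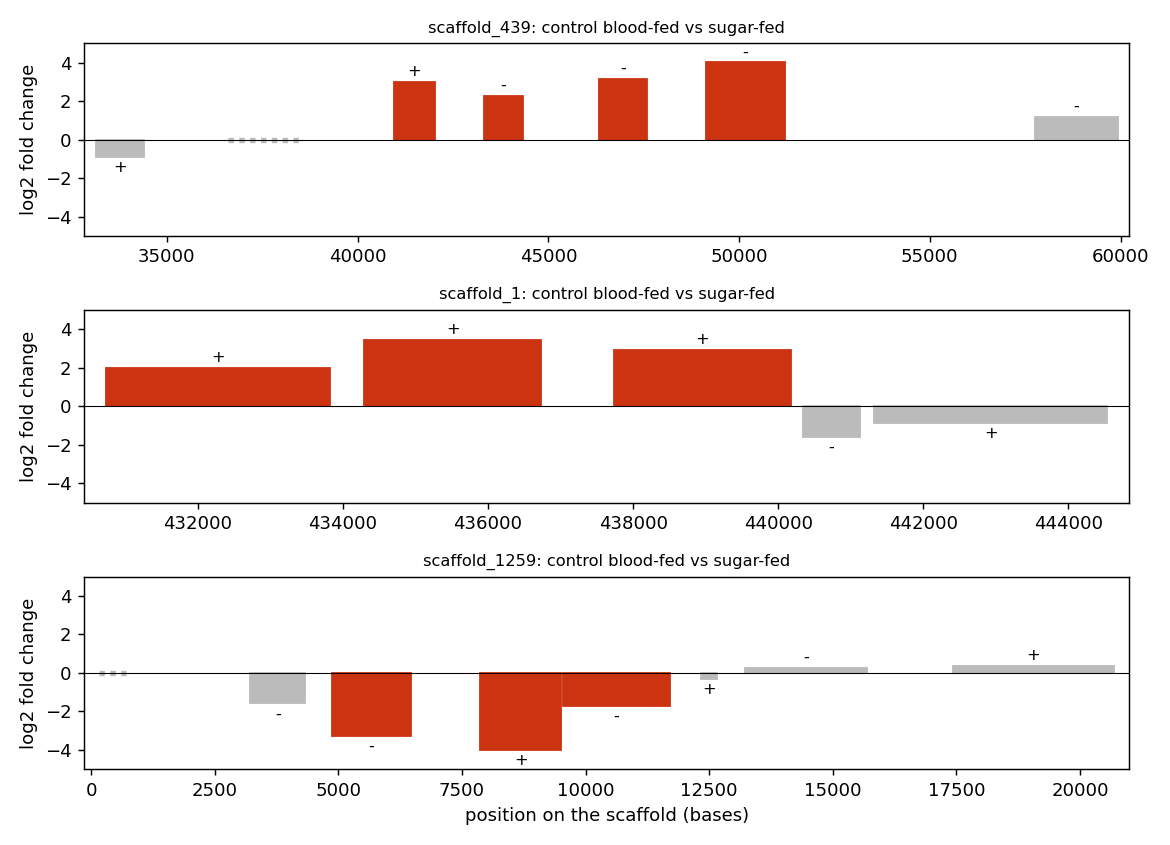
Boxes span gene models along the 3 longest runs and their flanks, with position in bases on the horizontal axis and the log2 fold change of control blood-fed over sugar-fed midguts as box height. Signs give the strand, red boxes passed an edgeR adjusted p of 0.05, and dotted bars were not tested. The run on scaffold 439 spans 40942 to 51204.

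P. vivax-fed midguts were also compared with sugar-fed ones, which measures the meal and the live parasite together. Here 83 genes were higher and 37 lower of 7831 tested, with median log2 fold changes of 4.11 and -2.61. The 83 higher genes took 0.224% ± 0.143 of counts in sugar-fed and 4.51% ± 0.739 in P. vivax-fed libraries, and the 37 lower genes took 0.659% ± 0.203 and 0.122% ± 0.0271 (SD, n = 3). ADAC006140 on scaffold 95 (143417 to 146309, minus strand) rose from 9.29 ± 5.52 to 1457 ± 209 CPM (SD, n = 3), with a log2 fold change of 7.31 (SE 0.68, edgeR adjusted p = 0.00331). Its level after control blood was 1766 ± 256 CPM. ADAC004047 on scaffold 2081 (166 to 783, plus strand) had 1, 3 and 2 counts in sugar-fed and 79, 107 and 762 in P. vivax-fed libraries. Its pooled ratio was 109, with a 95% counting interval of 49.7 to 297 (edgeR adjusted p = 0.0380). Most of these counts came from P. vivax-fed library 3: without it the log2 fold change went from 7.29 to 4.87 and the call was lost (edgeR adjusted p = 0.0717). It was lost in 11 of 21 alternatives, limma-voom among them (adjusted p = 0.105). The 2 named falls were the same genes as after control blood: ADAC008119 with a log2 fold change of -5.04 (SE 0.76, edgeR adjusted p = 0.0155) and ADAC000651 with -4.23 (SE 0.87, edgeR adjusted p = 0.0445). The call of ADAC008119 was lost in 5 of 21 alternatives, and its log2 fold change was -3.77 without sugar-fed library 1. That of ADAC000651 was lost in 11 of 21, among them each fit without a control blood-fed or P. vivax-fed library, and its log2 fold change was -2.57 without sugar-fed library 1. Of the 13 mitochondrial genes, 0 passed the threshold in edgeR, DESeq2 or limma-voom, and 3 had an unadjusted edgeR p under 0.05.

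Log2 fold changes trended with gene length here too (Spearman rho 0.219) and with exon number (rho 0.253), and the median length was 1341 bases in the higher and 1608 in the lower genes.

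This count also moved with each library: it was 553, 33 and 965 without sugar-fed libraries 1, 2 and 3, 36, 30 and 36 without control blood-fed libraries 1, 2 and 3, and 43, 28 and 22 without P. vivax-fed libraries 1, 2 and 3. DESeq2 called 998 genes, a fit of the 6 libraries compared 9, glmTreat 50 and an adjusted p of 0.01 left 11. The majority of higher genes turned over with DESeq2, at 369 higher and 629 lower, and without sugar-fed library 3, at 249 and 716, and it was 281 and 272 without sugar-fed library 1.

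**Figure D4:**
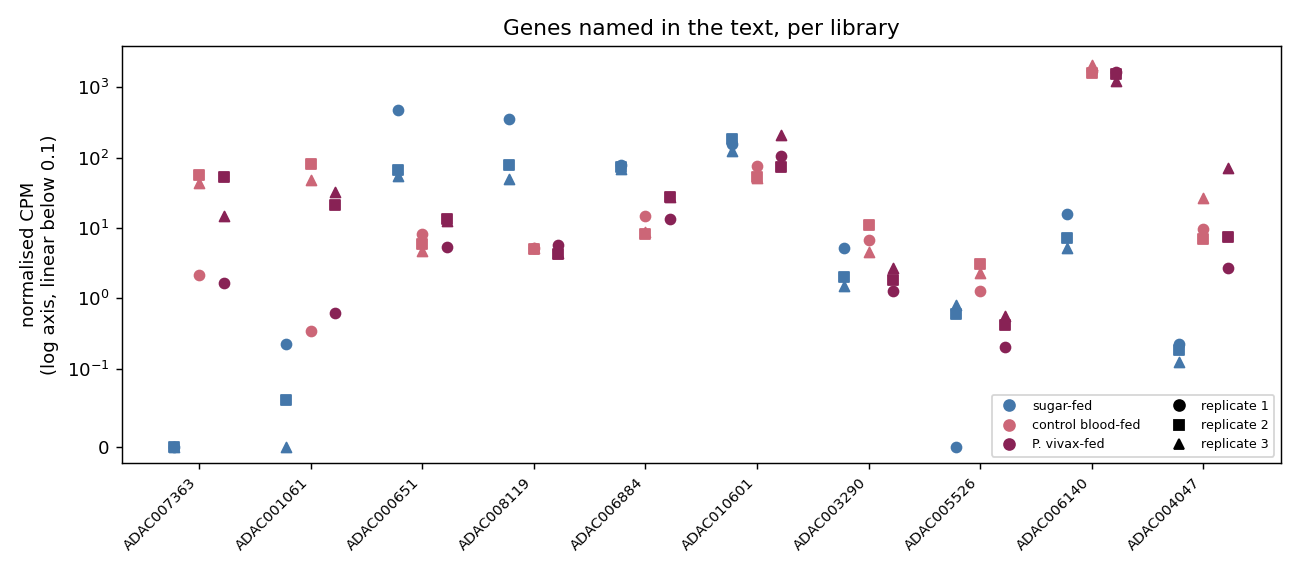
Normalised CPM of each named gene in each library, on an axis that is logarithmic above 0.1 and linear below. Colours give the meal and shapes the replicate number. ADAC006140 lies between 5.17 and 15.6 CPM in sugar-fed libraries and between 1222 and 2052 CPM in the 6 blood-fed libraries.

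Many genes called against sugar were called after both blood meals. Of the higher genes, 83 were called in both comparisons, where independent lists would share 2.11. Of the lower genes, 35 were called in both, where independent lists would share 1.15. Simulated unchanged groups against the same sugar-fed libraries shared 0 in either direction, but too few genes were called there for any to be shared, so that 0 is no yardstick for the overlap. Across 7831 genes, which are not independent replicates, 92.8% had the same sign in the 2 comparisons, against 66.8% in the simulations. The log2 fold changes correlated at r = 0.961, against 0.506 in the simulations. Their covariance was 1.82 against 0.244 simulated, a difference of 1.58. The 3 sugar-fed libraries cannot be divided so that each part keeps 2, so part of the excess may come from the shared controls. The simulations gave all libraries of a gene the same spread, although sugar-fed library 1 lay apart from the others. The simulated sign share, correlation and covariance may therefore be too low. Same-numbered libraries of the 2 blood-fed groups also deviate together, with correlations of 0.342 to 0.609, and the simulations drew them independently, so part of the correlation and covariance may come from that as well. Leaving out a library gave overlaps of 12 to 276 higher genes and 0 to 707 lower genes.

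P. vivax-fed and control blood-fed midguts were compared to separate the live parasite from the meal. No gene differed past the threshold: edgeR called 0 of 7831, with 17 at an unadjusted p under 0.05 where chance alone gives 392. DESeq2 and limma-voom also called 0, with 37 and 27 genes at an unadjusted p under 0.05. Counts so far below chance mean that these p-values ran too large. The 0 calls are thus weak evidence that the groups were alike. The log2 fold change lay between -1 and 1 for 97.2% of genes. The smallest p-values upward belonged to ADAC006884 on scaffold 204 (32641 to 34096, minus strand), at 10.6 ± 3.74 and 22.99 ± 8.17 CPM in control blood-fed and P. vivax-fed libraries, and to ADAC010601 on scaffold 489 (15741 to 17555, minus strand), at 59.98 ± 13.4 and 130 ± 71.3 CPM (SD, n = 3). Those downward belonged to ADAC003290 on scaffold 1802 (2008 to 3386, plus strand), at 7.51 ± 3.38 and 1.95 ± 0.732 CPM, and to ADAC005526 on scaffold 18 (396176 to 398818, minus strand), at 2.19 ± 0.895 and 0.398 ± 0.180 CPM (SD, n = 3). Their log2 fold changes were 1.11 (SE 0.44), 1.12 (SE 0.47), -1.96 (SE 0.62) and -2.49 (SE 0.82), each with an edgeR adjusted p above 0.999. Of the 13 mitochondrial genes, 0 passed the threshold in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted edgeR p under 0.05.

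The spread limited this comparison, with a biological coefficient of variation of 0.546 over 9 libraries and 0.346 over the 6 blood-fed ones. In those 6, edgeR still called 0 genes, with 119 of 7603 at an unadjusted p under 0.05. With the 6 libraries paired by number, edgeR called 0, with 312 of 7603 at an unadjusted p under 0.05. Both numbers are still below the chance share, the paired one by less. DESeq2 with pairing called 8, all lower, while DESeq2 without pairing called 0. The paired and DESeq2 fits of these 6 libraries were added after the data were seen, and the 8 calls came from 1 of 4 fits of them.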

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

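Fits with a replicate block after dropping sugar-fed library 1, DESeq2 and paired fits of the 6 blood-fed libraries, the overlaps under other scalings, filters, limma-voom and left-out libraries, and all alternatives for the mitochondrial genes, the neighbouring pairs and the genes kept in every left-out fit were chosen after seeing the data; the other alternatives were chosen before the data were examined. Counts against sugar kept within 1.5 times under other scalings, other filters and limma-voom, and moved under most others. For control blood against sugar (442 genes), DESeq2 gave 1475, glmTreat 237, the 6 libraries compared 20 and an adjusted p of 0.01 gave 10. Leaving out a library gave 12 to 1603. For P. vivax blood against sugar (120 genes), the same settings gave 998, 50, 9 and 11, and leaving out a library 22 to 965. Shared higher genes (83) numbered 350 with DESeq2, 9 at an adjusted p of 0.01 and 12 to 276 without a library. Shared lower genes (35) numbered 54 with upper-quartile factors, 585 with DESeq2, 0 at an adjusted p of 0.01 and 0 to 707 without a library. Why the counts moved was not tested; leaving out sugar-fed library 1 or 3 raised both counts against sugar although fewer samples remained.

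With the replicate block, control blood against sugar had 180 genes, 117 higher and 63 lower, P. vivax blood against sugar 73, and 8 lower genes were shared. The block without sugar-fed library 1 gave 940 and 594, with 1 of the 13 mitochondrial genes past the threshold after control blood. Sugar-fed libraries share only a number with the others: deviations of same-numbered libraries correlated at -0.00642, 0.157 and -0.212 with control blood-fed and at -0.150, 0.517 and -0.305 with P. vivax-fed ones, and 2 of 6 libraries were closest to their own number in each case. P. vivax blood against control blood kept 0 calls in 23 of 24 alternatives, the exception being DESeq2 on 6 libraries with the replicate block (8). No named gene changed direction. ADAC006140 passed in 21 of 21 alternatives, with adjusted p up to 0.0188, and the other named calls against sugar were lost in 5 to 11 each. Small simulated changes were not found: with all 9 libraries, 2-fold changes were recovered in 0% of cases in each comparison. Recovery of larger ones varied with the libraries fitted. For control blood against sugar, the simulations held fewer changed genes than were called, so that recovery may not carry over to the data.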

Other observations

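The 3 patterns weighed here were first noticed in these data. The bound for the depth test was set after the number of genes detected per library had been seen, and the counts over left-out libraries and the neighbour counts under other settings were added after the main calls were known; the bounds of the other tests were set before the values they concern were seen.

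A small set of genes rose after blood whichever library was left out. Against sugar, 12 genes passed the edgeR threshold with control blood in the fit of all libraries and in each of the 9 fits without 1 library, with log2 fold changes of 4.80 to 7.59. All 12 were higher, and all 12 were also called with P. vivax blood. Together they took 0.00609% of counts in sugar-fed, 0.591% in control blood-fed and 0.509% in P. vivax-fed libraries. With P. vivax blood the same criterion left 16 genes, all higher, with log2 fold changes of 3.19 to 7.31, and 11 genes met it in both comparisons, ADAC006140 among them. No falling gene met it in either comparison, but none could have. Without control blood-fed library 2 or 3 the fit called 0 lower genes for control blood against sugar. Without P. vivax-fed library 1 or 3 the fit called 0 lower genes for P. vivax blood against sugar. This absence therefore tells nothing about the falling genes. The 12 rising genes are likewise the 12 called in the fit without control blood-fed library 3.

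Neighbouring genes rose together after control blood more often than calls placed at random: among 5434 neighbouring pairs tested, 20 had both genes higher, against 3.46 in permutations (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give; adjusted p = 4e-04 over 8 tests). Reads shared between overlapping or abutting models would confine this to close pairs, but among pairs at least 1000 bases apart 15 had both genes higher against 1.85 permuted, while falling pairs numbered 11 against 5.22 permuted (adjusted p = 0.034) and 2 such distant ones against 2.77. After P. vivax blood, 3 pairs were both higher against 0.613 permuted (adjusted p = 0.0368), all 3 at least 1000 bases apart, and 0 were both lower. Only the rising pairs after control blood, at any distance, were counted under the alternatives. There 0 pairs were found in the fit of 6 libraries, at an adjusted p of 0.01 and without control blood-fed library 1, 2 or 3. Those settings called 10 to 34 genes higher, and permutations gave at most 0.085 pairs. In the other settings the excess had a one-sided permutation p under 0.05. Reads shared between similar gene copies could give the same picture and were not tested, since no sequence was used here, and no biological explanation was tested.

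Sugar-fed library 1 stood apart from the other 8, and lower depth, a blood-fed pool under the wrong label and few starting molecules were each tested. Its total of 14049392 counts was not low, yet it had 5683 genes with at least 10 counts, against 7007 to 8001 in the others. This alone speaks against lower depth. Thinning to the smallest total of 8072117 counts gave 4968 genes against 6798 to 7609. It adds little, since it could hardly have come out otherwise. The label was tested over the 921 genes called without it for control blood against sugar. Its shift from sugar-fed libraries 2 and 3 was at the median -0.577 of the blood-meal shift (95% bootstrap interval -0.705 to -0.476). At the median it thus moved away from the blood-fed libraries. The ratio was given under a single scaling, and the TMM factor of this library was 0.320, so part of its size may come from scaling. Across genes, this library correlated at 0.756 and 0.783 with the sugar-fed and at 0.658 to 0.742 with the blood-fed libraries. At 1000 or more expected counts, the SD of its log2 ratio to libraries 2 and 3 was 2.59 times that of library 2 against 3 (1.81 to 3.67). That SD was 2.11 there and 2.09 at 20 to 50 expected counts, where few molecules as the whole cause would have made it fall with abundance. At 20 to 50 expected counts, 23.7% of genes had 0 counts in it with scaling to the total and 3.47% with TMM, against at most 2.62% and 2.63% in the other 8, so few molecules may add to its spread at low counts. RNA degradation, other tissue in the pool and GC content were not tested and may each account for it; the labels name no biological difference, so none was tested.

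Blood-fed libraries with the same number deviated together across the 2 blood meals, as if each number marked a shared day, mosquito cohort or blood donor, which no label states. A trend with gene length that differs between libraries was tested, since deviations correlated with length at -0.467 to 0.430. After that trend was removed, the lowest of the 3 same-number correlations was 0.333, down from 0.342, so length may account for only a small part. A shared collection or a shared library batch would both give this and cannot be separated without dates.

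The 6 libraries of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. For control blood against sugar the real split gave 442 genes and the highest other 0, so 1 of 10 gave as many. For P. vivax blood against sugar the real split gave 120 and the highest other 0, again 1 of 10. For P. vivax blood against control blood all 10 splits gave 0.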
